A study of Mus musculus with 24 samples.

How the data were processed

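RNA-seq was analysed for 7 mouse libraries of pluripotent cells, all from male F1 cells of 129X1/SvJ and MSM/Ms parents, as the labels give them. Induced pluripotent stem cells (iPSCs, the naive-like state) gave 4 libraries, named by clone as iPSC 1, 7, 9 and 13. Cells reprogrammed to the primed state of epiblast stem cells (iEpiSCs) gave 2 libraries, B1 and F1. Embryo-derived epiblast stem cells (EpiSCs, primed) gave 1 library, EpiSC 12. The series holds 24 samples, and the other 17, of DNA methylation, were not analysed here. Per the labels' protocols, iPSCs grew on mitotically inactive embryonic fibroblasts with serum and leukemia inhibitory factor (LIF), EpiSCs in a serum replacement with basic FGF and a ROCK inhibitor, and iEpiSCs in serum with basic FGF, Activin A and an antibody against LIF. The medium therefore differed between all 3 groups. EpiSC 12 was at passage 3 and the other 6 libraries were at passage 4.

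The deposited values are RPKM (reads scaled by gene length and by library total), made by the authors, with 1 column per library and no pooling of replicates. Per the labels' protocols, the libraries came from a stranded poly(A) kit. The submitters' processing notes name cutadapt 1.9.1, Bismark 0.15.0, Bowtie2 2.2.8 and 2.2.5, TopHat2 2.1.0, Cufflinks 2.2.1 and STAR, and the build mm10, without roles. The name of the deposited table holds STAR, though the notes do not state the steps behind it. The annotation release and the library total used for scaling are not given in the sources used here. Each value sums over both parental alleles. A poly(A) library also misses most non-polyadenylated histone transcripts.

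The table holds 52610 rows with 52546 distinct gene identifiers, and 112 rows share an identifier with another row. A symbol held by several rows was taken from its row of highest mean. Of the identifiers, 49085 occur in GENCODE M21 with the same version, and 49016 of these have the same coordinates once the deposited starts, which count from 0, are raised by 1. Coordinates below are on mm10 and count from 1. All 1570 rows of chromosome Y and all 37 rows of the mitochondrial chromosome are listed at 0 in every library, although the cells are male. An exact 0 in this table can therefore be an excluded or failed estimate, so genes are called "listed at 0" and no fold is given against a group at 0. The Y-linked list had no tested member for the same reason. Very short genes have inflated RPKM, which an added alternative leaves out.

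Read totals are not given in the sources used here. The RPKM sum per library lay between 811943 and 919994. Low values move in steps of 1 read, so relative depth was read from the most frequent ratio between libraries among rows under 0.06 RPKM. Between 46.7% and 59.3% of those rows lay within 0.02 log2 units of that ratio. Relative to iPSC 7, depth was 1.37 for iPSC 1, 1.19 for iPSC 9, 1.32 for iPSC 13, 1.01 for iEpiSC B1, 0.873 for iEpiSC F1 and 1.14 for EpiSC 12. Relative depth thus followed the groups in part, being higher in iPSC 1, 13 and 9 than in both iEpiSC clones. Its absolute size and the counting error of a value are unknown. The highest correlation of any pair of libraries was 0.977, so none was a copy of another.

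RPKM was compared as log2(RPKM + 1) for the 15338 rows with at least 1 RPKM in at least 1 library. Changes are on this scale, which understates the change of low genes. limma 3.58.1 in R 4.3.3 was fitted to all 7 libraries with a mean per group (lmFit, contrasts.fit, eBayes with trend), two-sided. The fit had 4 residual degrees of freedom, 2.3 prior degrees of freedom and no covariate. The lone EpiSC library adds no residual degree of freedom and is assumed to vary like the others. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all rows of a comparison. Every adjusted p below is from this limma fit unless another test is named. Clones are separate by their labels, but nothing says that they came from separate reprogramming experiments, so p-values measure the spread between these clones.

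The 19 gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 18 lists with at least 3 tested members. An alternative estimated this correlation from the data, and camera then tests with the 4 residual degrees of freedom of the fit. This alone raises its p-values, so a list that fails there does not show that correlated genes made its call. The lists were naive pluripotency, general pluripotency, primed epiblast, primitive streak and mesendoderm, extraembryonic endoderm, trophoblast, neural, fibroblast and feeder, maternally and paternally expressed imprinted genes, DNA methylation and imprint maintenance, germline methylation-sensitive genes, glycolysis, cytochrome c oxidase, LIF and STAT3 response, Activin and Nodal response, FGF and ERK response, replication-dependent histones, and Y-linked genes. The spread of the 53 tested imprinted genes between iPSC clones (SD of the log2 value) was set against 10000 random lists of the same size, drawn within 20 bins of mean expression, as a description with no p-value. The comparisons of iEpiSC and EpiSC with iPSC share their iPSC libraries, so their likeness was set beside 100 simulated data sets with unchanged groups.

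Genes were named by a rule. In each comparison it took the 12 called genes with the largest rise and the 12 with the largest fall whose groups did not overlap, leaving out predicted genes and small RNA genes. From each list it took up to 4 called members with the largest change, or up to 2 members where none was called. It also took 24 genes in every comparison, and the 8 imprinted genes with the largest SD between iPSC clones. Lists, tests, alternatives and this rule were fixed before the data were examined. The alternatives covered the pseudocount, the filter, scaling, the variance prior, a fold threshold and each left-out library. The values of 1 gene that the rule takes are not reported here, and it was left out of the test for distant clones. Alternatives and gene sets chosen after seeing the data are named as such.

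The fit was tested on simulated data of 15338 genes with 50 changed genes at each of 4 sizes per comparison. For iEpiSC minus iPSC it recovered 66% of genes with a log2 change of 1 and 96% with a change of 2. For EpiSC minus iPSC it recovered 38% and 84%, and for iEpiSC minus EpiSC 30% and 74%. False calls numbered 9, 8 and 7. Of 200 unchanged simulated lists, camera gave 7 an unadjusted p under 0.05. The changed genes and these lists were drawn only from the more highly expressed genes. Simulated genes varied independently of each other, so this count does not apply to lists of correlated genes.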

Results

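The data are RNA levels (RPKM) in 4 iPSC clones, 2 iEpiSC clones and 1 EpiSC line of mouse, which together ask how expression, and that of imprinted genes in particular, differs between cells reprogrammed to naive or primed pluripotency and primed cells derived from embryos. Imprinted genes are expressed mainly from the allele of 1 parent, and the study's title concerns DNA methylation at their loci. Between 12453 and 13161 genes per library had at least 1 RPKM. The pairwise Pearson correlation across genes of log2(RPKM + 1) was 0.945 to 0.977 among iPSC clones and 0.973 between the iEpiSC clones. It was 0.952 to 0.954 between EpiSC and iEpiSC, 0.905 to 0.932 between iEpiSC and iPSC, and 0.886 to 0.917 between EpiSC and iPSC. Genes are not independent replicates, so these values carry no test.

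The first comparison asked how primed reprogrammed cells differ from naive reprogrammed cells. All 20 tested naive pluripotency genes were lower in iEpiSCs than in iPSCs. Dppa5a, an RNA-binding protein of naive cells, fell from 2779 ± 1015 RPKM (SD, n = 4) to 1.29 ± 0.234 RPKM (n = 2) in iEpiSCs, a log2 change of -10.17 ± 0.34 (SE, adjusted p = 0.000264). Tdh, threonine dehydrogenase, fell from 434 ± 139 to 1.38 and 1.77 RPKM, and Zfp42 (Rex1), a zinc finger marker of naive cells, fell from 188 ± 81.2 to 0.459 and 0.836 RPKM. Esrrb, an orphan nuclear receptor, fell from 106 ± 37.1 to 1.15 and 2.25 RPKM. Nanog fell less, from 160 ± 31 to 61.3 and 60.1 RPKM (log2 change -1.36 ± 0.18, adjusted p = 0.00677). Pou5f1 (Oct4) was at 2792 ± 287 RPKM in iPSCs and 2144 and 2183 RPKM in iEpiSCs. Its log2 change of -0.362 ± 0.102 did not pass (adjusted p = 0.0522). Sox2 fell (log2 change -1.13 ± 0.16, adjusted p = 0.00756). Pou5f1 passed in 5 of 16 alternatives, and the calls of Nanog and Sox2 were lost in 2 each.

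Of the 17 tested genes of the primed epiblast, 11 rose and none fell. Fgf5, a growth factor of the epiblast, stood at 26 ± 18.7 RPKM in iPSCs and 126 and 114 RPKM in iEpiSCs, Otx2 at 22.2 ± 10.8 against 84.2 and 85.1 RPKM, and Car14 at 7.04 ± 2.19 against 71.8 and 71.7 RPKM. The calls of Fgf5 and Otx2 (adjusted p = 0.0355 and 0.0347) were lost in 6 of 16 alternatives each, and that of Car14 in 0. The largest rise among named genes was that of Cer1, a secreted antagonist of Nodal, BMP and Wnt, at 15.9 ± 19.4 RPKM in iPSCs and 443 and 422.5 RPKM in iEpiSCs (log2 change 5.41, adjusted p = 0.0161). Hesx1, a homeobox gene of the anterior epiblast, rose from 0.245 ± 0.102 to 14 and 17.5 RPKM, and Plod2, a collagen lysyl hydroxylase, from 17 ± 2.03 to 185 and 205 RPKM (adjusted p = 0.000264). Of the 10 extraembryonic endoderm genes, 4 rose and 1 fell; Sox17, Gata6, Gata4 and Foxq1, transcription factors also used in definitive endoderm, were those that rose. Of the 12 primitive streak and mesendoderm genes, Cer1 alone was called. iPSC 1 was the highest iPSC clone for some genes of this list. T was at 201 RPKM there (16.7 to 97.4 RPKM in the other clones), Mixl1 at 14.6 (1.47 to 4.99), Lhx1 at 26.3 (0.87 to 5.14) and Cer1 at 44 RPKM (2.93 to 13.4). The test for single distant clones, described below, did not pick out iPSC 1 for this list. Without iPSC 1 the list was called higher in iEpiSCs at the preset correlation (camera adjusted p = 0.00604). With a correlation estimated from the data (0.734 for this list), its camera adjusted p over all libraries was 0.761.

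Of all tested genes, 3206 were called, 1413 higher and 1793 lower in iEpiSCs. The balance depends on the scaling: with quantile normalization 1831 were higher and 1446 lower. The naive list (median log2 change -3.64, camera adjusted p = 9.53e-16), the germline list (-1.43, 1.8e-06) and the LIF and STAT3 list (-1.18, 3.09e-05) were lower. The primed epiblast list (1.13, 3e-06), the glycolysis list (0.315, 0.00257) and the extraembryonic endoderm list (0.841, 0.00761) were higher. None of these 6 lists passed with an estimated correlation, where their adjusted p was 0.281 to 0.432. The estimated correlation of the LIF and STAT3 list was only 0.0387, yet its camera adjusted p became 0.281. With 4 residual degrees of freedom in that test, these values do not tell whether correlated genes made the calls. Adjusted over the list alone, 20 naive, 12 germline and 8 LIF and STAT3 genes were lower and none higher. By the same measure 12 primed epiblast genes were higher and 1 lower, 11 and 3 in the glycolysis list, and 4 and 1 in the endoderm list. The count of genes rests on few clones: it was 792 without iEpiSC B1, 420 without iEpiSC F1, 1998 without iPSC 1 and 1338 without iPSC 13. Of 75 called genes named here, 29 kept their call with each iPSC and iEpiSC library left out.

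Genes that act in DNA methylation moved both ways, 3 higher and 6 lower of 18 (10 passed adjusted over the list alone, and camera gave an adjusted p of 0.123). Dnmt3l, a cofactor of the de novo methyltransferases, fell from 165 ± 55.8 RPKM to 0.887 and 1.69 RPKM (log2 change -6.13 ± 0.35, adjusted p = 0.000849). Zfp57, which protects methylated imprints, fell from 151 ± 18.1 to 15.6 and 15.9 RPKM (log2 change -3.17 ± 0.13, adjusted p = 0.000317). The dioxygenases Tet1 and Tet2, which oxidise methylcytosine, fell from 21.2 ± 2.71 to 7.78 and 6.04 RPKM and from 9.33 ± 2.04 to 0.371 and 0.196 RPKM. Dnmt3b, a de novo methyltransferase, rose from 219 ± 35.9 to 437 and 418.5 RPKM (adjusted p = 0.00986), a call lost without iEpiSC B1 (adjusted p = 0.078) or F1 (0.0831). Dnmt1, the maintenance enzyme, fell by 0.36 on the log2 scale (adjusted p = 0.0192), a call also lost without B1 (0.0841) or F1 (0.0821). Dnmt3a (138 ± 39.1 against 165 and 140 RPKM) and Uhrf1 (216.5 ± 19.7 against 229 and 207 RPKM) did not pass.

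Of the 13 tested germline genes whose promoters are known to be silenced by methylation, 11 were called lower and none higher. Of these 11, 8 were listed at 0 in both iEpiSC clones, where a 0 can also be a failed estimate and relative depth was 1.01 and 0.873 (1 to 1.37 in iPSCs), and 3 (Sycp3, Stk31 and Tuba3a) had a value above 0 in at least 1. Rpl10l stood at 60.7 ± 38.1 RPKM in iPSCs, Ddx4 at 5.44 ± 1.27 and Mael at 8.45 ± 4.99 RPKM, and all 3 were listed at 0 in both iEpiSC clones and in EpiSC 12. Sycp3 fell from 17.2 ± 5.63 to 0.971 and 0.485 RPKM. In the LIF and STAT3 list 8 of 12 genes fell, among them Pim1, from 55.5 ± 9.92 to 10.8 and 9.67 RPKM, and Klf4, from 107 ± 51.5 to 4.56 and 2.94 RPKM. In the glycolysis list 10 of 18 genes rose and 3 fell. Ldha, lactate dehydrogenase A, rose from 1283 ± 77.1 to 2619 and 3056 RPKM, and the glucose transporter Slc2a3 from 333 ± 82.2 to 561 and 717 RPKM, while Pdk1 and Pfkp fell. The Slc2a3 call (adjusted p = 0.0491) was lost in 9 of 16 alternatives, those of Pdk1 and Pfkp in 4 each and that of Ldha in 0. The fibroblast and feeder genes had a median change of -0.773 (3 of 18 lower, 4 adjusted over the list alone, camera adjusted p = 0.0863). Among iPSCs the fibroblast collagen Col3a1 stood at 36.1 RPKM in clone 9 and 10.7 to 15.8 RPKM in the other clones.

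**Figure D1:**
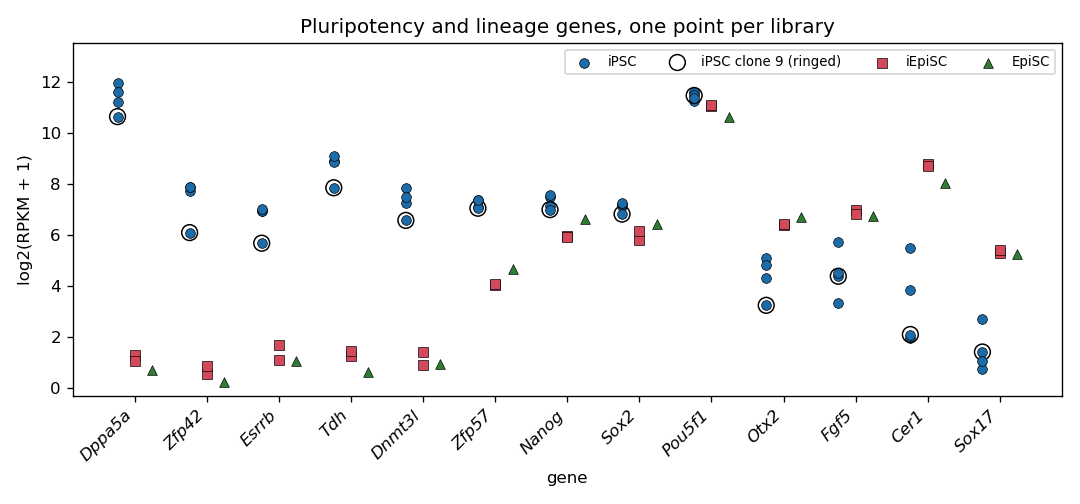
Each point is 1 library, with the gene on the horizontal axis and log2(RPKM + 1) on the vertical axis, for 4 iPSC, 2 iEpiSC and 1 EpiSC libraries. Dppa5a was at 2779 RPKM in the mean of iPSCs and under 2 RPKM in every primed library, while Pou5f1 lay between 1608 and 3147 RPKM in all 7, and the ring marks iPSC clone 9.

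The second comparison set the embryo-derived EpiSC line against the iPSC clones. Of the 20 naive genes, 17 were called lower, of which Dppa3 and Tcl1 were listed at 0 in EpiSC 12; Dppa5a fell to 0.644 RPKM, Tdh to 0.565, Esrrb to 1.10 and Zfp42 to 0.174 RPKM. Primed epiblast genes rose in 7 of 17 cases, among them Car14 (58.3 RPKM), Krt18 (494 against 110 ± 35.4 RPKM), Sox4 and Sox3, while Fgf5 (106 RPKM, adjusted p = 0.0994) and Otx2 (105 RPKM, adjusted p = 0.0597) did not pass. Otx2 passed in 5 of 16 alternatives and Fgf5 in 1. Between iEpiSCs and EpiSC 12 the log2 changes were 0.171 ± 0.838 for Fgf5 and -0.302 ± 0.7 for Otx2, within their SE. The largest rises were those of Pga5, a pepsinogen (173 against 1.07 ± 0.568 RPKM), Spink1, a trypsin inhibitor (566 against 18.2 ± 12.3 RPKM), Sfrp5, a secreted Wnt antagonist (62.6 against 0.653 ± 0.122 RPKM), and Hesx1 (33.9 RPKM). Dnmt3l (0.955 RPKM), Zfp57 (24.9 RPKM) and Tet1 (10.0 RPKM) were lower, and Dnmt3b, at 228 RPKM, was not called (adjusted p = 0.822). Of the 10 general pluripotency genes, 4 fell, Pou5f1, Tdgf1, L1td1 and Utf1.

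In total 2135 genes were called, 1061 higher and 1074 lower in EpiSC 12. The lists called lower were naive pluripotency (camera adjusted p = 2.89e-14), germline (4.01e-06, all 5 called genes listed at 0 in EpiSC 12), general pluripotency (0.00151), cytochrome c oxidase (0.0062, with none of 12 genes called), LIF and STAT3 (0.00637) and DNA methylation (0.00659). Those called higher were primed epiblast (0.000251), fibroblast and feeder (0.00117), maternally expressed imprinted genes (0.00153) and extraembryonic endoderm (0.00279). With an estimated correlation none passed, and their adjusted p was 0.257 to 0.602. Adjusted over the list alone, 18 naive, 11 germline, 6 general pluripotency, 0 oxidase and 6 LIF and STAT3 genes were lower and none higher, and 6 fibroblast and 6 endoderm genes were higher and none lower. Higher and lower were 2 and 7 methylation, 13 and 1 primed epiblast, and 11 and 2 maternally expressed genes. Fibroblast markers moved with this comparison: Dcn, a proteoglycan of connective tissue, stood at 21.5 RPKM in EpiSC 12 against 2.4 ± 1.69 RPKM in iPSCs, and Lum, Mmp2 and Thy1 were higher too. The count was 620 without iPSC 13, 1025 without iPSC 1, 1064 and 1068 without iEpiSC B1 and F1, and 3219 without iPSC 9. Of 75 called genes named here, 45 kept their call with each of these libraries left out. With the fibroblast score as a covariate, an alternative chosen after seeing the data, the count was 70. This score is the mean log2 value of the fibroblast list in each library. Its slope rests on differences among clones within the iPSC and iEpiSC groups, and EpiSC 12, alone in its group, adds nothing to it. The median SE of the 2135 genes then became 0.32 instead of 0.228 and their median absolute log2 change 1.05 instead of 1.24. The changes of Rian (4.41 ± 1.52) and Mirg (3.55 ± 1.01) stayed about as large while their calls ended, and that of H19 went from 3.48 ± 0.68 to 2.08 ± 0.75. The slope of the score can carry any other difference between clones, so these values do not tell what fibroblast RNA contributes.

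Some immediate-early genes, which respond to stimuli within minutes, were among the largest rises in EpiSC 12; they were grouped under this name after their values were seen. Fosb stood at 261 RPKM against 12.8 ± 3.46 RPKM in iPSCs (log2 change 4.28 ± 0.59, adjusted p = 0.0118), Egr2 at 49.2 against 1.39 ± 0.784 RPKM, Egr4 at 20.5 against 0.391 ± 0.204 RPKM and Egr1 at 215 against 39 ± 11.2 RPKM. In the FGF and ERK list, which holds Egr1, 2 of 11 genes rose, and Etv4 and Etv5, targets of ERK signalling, fell to 10.2 and 31 RPKM from 40.4 ± 6.7 and 97.5 ± 6.06 RPKM (camera adjusted p = 0.766 for the list, 5 genes adjusted over the list alone).

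Imprinted genes were called in both directions in both comparisons. In iEpiSCs against iPSCs, 3 of 25 maternally expressed genes rose and 4 fell, and 4 of 28 paternally expressed genes rose and 5 fell (camera adjusted p = 0.674 and 0.995; 8 and 9 genes adjusted over the list alone). Asb4 (chromosome 6, 5383386 to 5433022) rose from 0.305 ± 0.181 to 15.4 and 15.2 RPKM, and Calcr on the same chromosome (3685680 to 3764714) from 0.461 ± 0.209 to 10.6 and 10.7 RPKM. Mest, at 70.8 ± 22.4 against 294 and 211 RPKM, Grb10, Peg3 and Snrpn were also higher, and Cobl, Gab1, Jade1 and Sfmbt2 were lower. The calls of Mest, Grb10, Peg3 and Snrpn were lost in 2, 8, 6 and 3 of 16 alternatives. Those of Cobl, Gab1, Jade1 and Sfmbt2 were lost in 0, 1, 0 and 8. Imprinting of Gab1, Jade1 and Sfmbt2 is known mainly from the placenta. In EpiSC 12 against iPSCs, 7 maternally expressed genes rose and 2 fell, and 5 paternally expressed genes rose and 4 fell. The maternal list was called higher there (median log2 change 1.03, camera adjusted p = 0.00153, and 0.257 with an estimated correlation), with 11 genes higher and 2 lower adjusted over the list alone. The paternal list was not (camera adjusted p = 0.799, 11 genes adjusted over the list alone). H19 (chromosome 7, 142575529 to 142578143), a noncoding RNA, stood at 509 RPKM against 50.3 ± 27.8 RPKM (adjusted p = 0.0266), and its neighbour Igf2 at 101 against 22.2 ± 5.82 RPKM (adjusted p = 0.0276). The H19 call was lost without iPSC 1 (0.0657) or 13 (0.0786) or iEpiSC B1 (0.0624) or F1 (0.0625), and the Igf2 call without iPSC 1 (0.0735) or 13 (0.0743). Cdkn1c was at 212 against 60.2 ± 6.76 RPKM and Dlk1 at 12.2 against 3.54 ± 0.517 RPKM. The fibroblast list was higher in EpiSC 12 as well (median 1.22). Kcnq1ot1 was at most 0.0109 RPKM in any library and was not tested.

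The maternally expressed noncoding RNAs Meg3, Rian and Mirg lie side by side on chromosome 12, from 109541001 (start of Meg3) to 109749460 (end of Mirg). They stood at 59.2, 178.5 and 21.6 RPKM in EpiSC 12. In iEpiSC B1 they were at 0.46, 3.79 and 0.234 RPKM and in F1 at 0.0774, 1.68 and 0.271 RPKM. Among iPSC clones Meg3 was at 17.2 RPKM in clone 7 and between 1.34 and 3.74 RPKM in the other clones, and Rian at 29.3 and between 3.22 and 11.1 RPKM. Rian (log2 change 4.03 ± 0.95, adjusted p = 0.0419) and Mirg (3.30 ± 0.64, adjusted p = 0.0258) were higher in EpiSC 12 than in iPSCs, and Meg3 did not pass (3.46 ± 0.99, adjusted p = 0.0661). The Rian call was lost in 10 of 16 alternatives, among them those without iPSC 1 (0.0605), 9 (0.0632) or 13 (0.106) or iEpiSC B1 (0.0886) or F1 (0.0885). The Mirg call was lost in 5 of 16, among them those without iPSC 13 (0.0753) or iEpiSC B1 or F1 (0.0663 for both), and Meg3 passed without iPSC 7 (0.0213). The differences between iEpiSC and EpiSC, of -5.59 ± 1.08 for Meg3, -5.65 ± 1.04 for Rian and -4.17 ± 0.70 for Mirg, did not pass over all genes (adjusted p = 0.0731, 0.0703 and 0.0635), except Meg3 without iPSC 7 (0.0478). Between iEpiSC and iPSC the adjusted p was 0.0991, 0.169 and 0.249, and Meg3 alone passed in 1 of 16 alternatives (0.0429). The paternally expressed Dlk1, at the same locus, was at 3.99 and 5.46 RPKM in iEpiSCs.

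**Figure D2:**
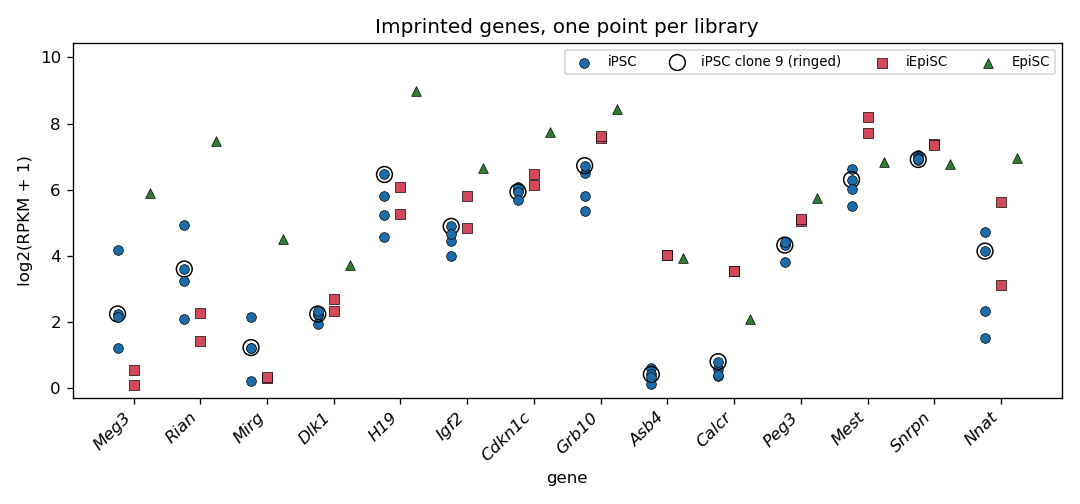
Each point is 1 library, with the imprinted gene on the horizontal axis and log2(RPKM + 1) on the vertical axis. Meg3 was at 59.2 RPKM in EpiSC 12, from 1.34 to 17.2 RPKM in iPSC clones and below 0.5 RPKM in both iEpiSC clones, and the ring marks iPSC clone 9.

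The third comparison set the reprogrammed against the embryo-derived primed cells, 2 libraries against 1. It called 107 genes, 36 higher and 71 lower in iEpiSCs, with 3128 at an unadjusted p under 0.05. The count was 803 without a filter. With the fibroblast score as a covariate it was 0, where the median SE of the 107 genes went from 0.219 to 0.438. The balance was unstable: 15 were higher and 16 lower with at least 1 RPKM in 2 libraries, 14 and 108 in eBayes without trend, and 0 and 24 without iPSC 13. Spp1, osteopontin, was at 154 and 141 RPKM in iEpiSCs and 941 RPKM in EpiSC 12 (log2 change -2.67 ± 0.14, adjusted p = 0.00163), and was the call with the lowest adjusted p among named genes. Fosb, Egr2, Egr4 and Nr4a1, all immediate-early genes, were lower in iEpiSCs, as was Gata3 (0.907 and 1.20 against 13.5 RPKM). Ldha, L1td1 (255 and 256 against 111 RPKM), Etv4 and Etv5 were higher. Glycolysis (1 gene higher, 9 adjusted over the list alone, camera adjusted p = 9.5e-07) and general pluripotency (1 and 5, 0.0136) were the lists called higher. The fibroblast list (0 genes called, 15 lower adjusted over the list alone, 1.18e-08) and the maternally expressed imprinted list (0 genes called, 8 lower and 1 higher adjusted over the list alone, 0.0121) were called lower. Col3a1 stood at 80.2 RPKM in EpiSC 12 and at 9.45 and 10.6 RPKM in iEpiSCs. With an estimated correlation the camera adjusted p of the lists called higher or lower here was 0.742 to 0.873. The general pluripotency call was lost in 4 of 9 alternatives, the maternal one in 2, and the glycolysis and fibroblast ones in 1 each. No naive gene of 20 was called (camera adjusted p = 0.976, 2 adjusted over the list alone), though Klf4 and Klf2 stood at 42.2 and 60.9 RPKM in EpiSC 12 against 2.94 to 6.91 RPKM in iEpiSCs. Of 26 called genes named here, 1 kept its call with each iPSC and iEpiSC library left out, and the count ran from 24 without iPSC 13 to 237 without iPSC 9.

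**Figure D3:**
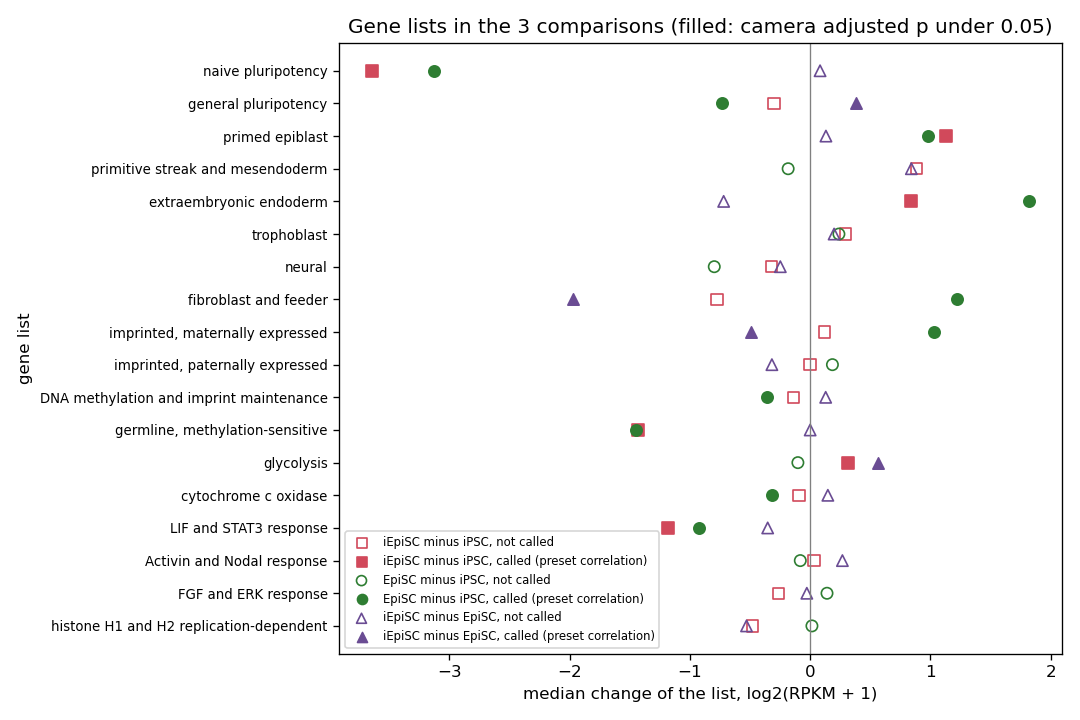
Each marker is the median change of a gene list on the log2(RPKM + 1) scale (horizontal axis) in 1 of the 3 comparisons, and filled markers passed camera with the preset correlation. The naive list lay at -3.64 for iEpiSC minus iPSC and -3.13 for EpiSC minus iPSC, and at 0.0823 between the primed groups.

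As analysed here the remaining lists held no camera call in any comparison. The primitive streak and mesendoderm list gained one under alternatives fixed beforehand, all at the preset correlation. It was higher in iEpiSCs than in iPSCs without iPSC 1 (camera adjusted p = 0.00604). It was higher than in EpiSC 12 with a pseudocount of 0.1 (0.0422) and without iPSC 1 (0.0093) or 7 (0.00917). With an estimated correlation (0.734) and all libraries, its camera adjusted p was 0.761 against iPSCs and 0.882 against EpiSC 12. Trophoblast genes had 1 higher and 1 lower of 8 in each comparison with iPSCs: Tfap2c was lower and Gata3 higher, and 4 and 2 passed adjusted over the list alone. Neural genes had 1 and 2 lower of 6, with Pax6 at 4.2 ± 0.965 RPKM in iPSCs and below 1 RPKM in the primed libraries. Activin and Nodal genes had 2 higher and 3 lower of 10 in iEpiSCs, Cer1 and Lefty1 against Smad7 and Tdgf1 among others. None of the 4 tested replication-dependent histone genes was called. The sign of the median, the mean and the camera direction differed for some of the lists without a camera call, such as the Activin and Nodal list, whose median was 0.0328 in iEpiSCs against iPSCs while camera pointed down.

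The 2 comparisons with iPSCs were alike. Across genes their log2 changes had a Pearson r of 0.713 and a Spearman rho of 0.612. Simulated unchanged groups set against the same iPSC libraries gave a mean r of 0.259 and at most 0.31 in 100 draws. The covariance was 0.533 against a simulated 0.0359. Genes varied independently of each other in these draws, so the draws understate how far such values can range without a change. With 2 iPSC clones given to each comparison, in 6 arrangements, r was 0.569 to 0.656. Both called 495 genes higher and 678 lower, and 17 genes were called in opposite directions.

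Imprinted genes differed more between iPSC clones than matched random lists. Their median SD was 0.341 against 0.228 for random lists, percentile 99.96. The difference between the iEpiSC clones lay at percentile 95.2. This was not particular to imprinted genes: the naive, mesendoderm and fibroblast lists lay at percentile 100 between iPSC clones, and 14 of the 18 lists lay above percentile 95. Leaving out iPSC 7, the percentile of imprinted genes was 97.56. Nnat had the largest SD among imprinted genes, with 1.89, 4.07, 16.7 and 25.4 RPKM in clones 1, 7, 9 and 13. Meg3 and Rian followed, and Zdbf2, Osbpl5, H19, Mirg and Tspan32 completed the 8 most variable.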

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

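The tests of explanations in this part were all chosen after the values were seen, while the test for single distant clones was fixed beforehand. A clone was picked out where its distance to the nearest other clone took up nearly the whole range of the 4 iPSC clones. Of 150 named genes tested, 8 met this (5.33%), and chance gives about 5%, so the number of such genes was near that of chance. This rate holds for independent, normally distributed values, which these genes need not be, so it is a rough guide. Clone 9 was the distant clone for 5 of the 8 genes. Among them was Ghrl, which the rule was bound to pick out because every other clone was listed at 0.

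In clone 9, Esrrb was at 50.65 RPKM (other clones 121.8 to 129.6), Zfp42 at 67.94 RPKM (210.9 to 238.9) and Dppa3 at 11.48 RPKM (28.83 to 33.5). The median log2(RPKM + 1) of the naive list was 4.92 in clone 9 (5.993 to 6.072 in the others) and that of the general pluripotency list 7.103 (7.443 to 7.473). Pou5f1 was at 2865 RPKM in clone 9 and 2468 to 3147 RPKM in the other clones. Srgn, a proteoglycan of blood and endothelial cells, was at 26.29 RPKM in clone 9 (0.04908 to 0.415), and Ghrl at 0.4341 RPKM where the other clones were listed at 0. In clone 7, Slc2a3 was at 211.1 RPKM (360.5 to 388.5), Peg3 at 13.15 RPKM (19.06 to 20.29) and Utf1 at 478.6 RPKM (309.5 to 327.3). The median of the paternally expressed imprinted list was 2.772 in clone 7 (3.405 to 3.536).

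The low naive genes of clone 9 could come from a lower share of pluripotent cells. Krt14 and Krt13, keratins of stratified epithelia, stood at 99.1 and 47.9 RPKM there against at most 0.504 and 0.329 RPKM in the other clones, so some other cells in this culture stay open. A lower share would lower naive and general pluripotency genes alike only if the other cells expressed neither. The median log2 ratio of clone 9 to the other clones was -1.06 over 20 naive genes and -0.291 over 10 general pluripotency genes, a difference of 0.767 (two-sided permutation test over genes, p = 0.00329, which describes these lists since genes are not independent). Clone 9 had already been picked out for these lists, and whether its other cells express general pluripotency genes is unknown. A lower share therefore stays open as the whole cause or a part.

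Clone 9 also had 478 genes more than 1 log2 unit above every other clone, against 117, 122 and 85 for clones 1, 7 and 13. RNA of feeder fibroblasts could carry 19.3% of the value of the median gene among these, when scaled by the most favourable of 18 fibroblast markers. It was under 50% for 325 of the 478 genes. This bound assumes that fibroblasts have the same profile in every library, and no fibroblast library was measured, so fibroblast RNA stays open for all 478 genes. No biological explanation was tested for clone 9, since the design names no difference between the clones.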

How the results depend on the processing

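Settings added after the data were seen were loci of at least 300 bases, leaving out iPSC clones 1 and 9 together, the fibroblast score as a covariate and bins of 20 genes. Over all settings 3363 values of named genes kept their direction and side of the threshold, 579 lost a call, 33 gained one and 21 turned direction; for gene lists, with the direction of camera, these numbers were 437, 25, 9 and 15. None of the values that turned was called under either setting. No paired analysis was possible because the clone numbers of the 3 RNA-seq groups share no number. The cause was not tested for the changes below, unless the setting itself tests fewer genes or libraries.

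Requiring an absolute log2 change of at least 1 left 1441 of 3206 genes for iEpiSC minus iPSC and 1392 of 2135 for EpiSC minus iPSC. The 107 genes of iEpiSC minus EpiSC became 47 with a pseudocount of 0.1, 803 without a filter, 31 with at least 1 RPKM in 2 libraries, 67 with quantile normalization, 61 with upper-quartile scaling and 40 without iPSC clones 1 and 9. With the fibroblast score as a covariate, which follows the groups in part, the counts were 2120, 70 and 0. For the genes called without it, the median absolute log2 change was 0.981, 1.05 and 1.59 with it (0.932, 1.24 and 1.70 without) and the median SE 0.224, 0.32 and 0.438 (0.178, 0.228 and 0.219), so the lost calls do not show that the differences went away. With an estimated correlation, 0 lists passed for iEpiSC minus iPSC, 0 for EpiSC minus iPSC and 0 for iEpiSC minus EpiSC. The test then has 4 residual degrees of freedom, so these counts do not show that correlation between genes made the calls. Quantile normalization turned the share of higher calls for iEpiSC minus iPSC from 44.1% to 55.9%, and upper-quartile scaling that for iEpiSC minus EpiSC from 33.6% to 21.3%. Under quantile normalization the cytochrome c oxidase list of EpiSC minus iPSC (adjusted p = 0.0562) and the general pluripotency list of iEpiSC minus EpiSC (0.0853) were lost, and the oxidase and DNA methylation lists of iEpiSC minus iPSC were gained as lower (0.0114 and 0.0353). A pseudocount of 0.1 gained the mesendoderm list of iEpiSC minus EpiSC (0.0422).

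With each library left out in turn, where a lone sample is assumed to vary like the other groups, iEpiSC minus iPSC ran from 420 (without F1) to 3549 (without 9), with 792 without B1, 1998 without 1 and 1338 without 13. EpiSC minus iPSC ran from 620 (without 13) to 3219 (without 9), with 1025 without 1, 1064 without B1 and 1068 without F1. iEpiSC minus EpiSC ran from 24 (without 13) to 237 (without 9), with 28 without 1, 51 without 7, 63 without B1 and 55 without F1. The lists called there numbered 2 (without B1) to 6 (without 7). Without B1 the general pluripotency and the maternally expressed imprinted lists were lost (adjusted p = 0.0667 for both), and without 9 the former (0.069). Gained were the mesendoderm list of iEpiSC minus EpiSC without 1 (0.0093) or 7 (0.00917) and of iEpiSC minus iPSC without 1 (0.00604), the fibroblast list of the latter without 1 (0.0323) or 7 (0.0162), and the oxidase list of iEpiSC minus EpiSC without 7 (0.045). Of the named called genes, 29 of 75, 45 of 75 and 1 of 26 kept their call in each of these fits. The spread percentile of imprinted genes between iPSC clones was 100 with a mean of at least 1 RPKM and 99.83 with bins of 20 genes, and ran from 97.56 (without 7) to 100 (without 1). Between iEpiSC clones, 95.24 became 99.11 with a pseudocount of 0.1, 97.93 with quantile normalization, 97.1 with a mean of at least 1 RPKM and 94.29 with bins of 20 genes. Absolute depth is unknown, so the counting error of low values was not assessed.

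The log2 changes that turned are given here. With the fibroblast score as a covariate, Dnmt3a became -0.171 for iEpiSC minus iPSC and 0.432 for EpiSC minus iPSC. For iEpiSC minus EpiSC with it, Zfp42 became -2.12, Esrrb -1.52, Dnmt3l -1.43, Sycp3 -0.774, Dnmt3a -0.603, Hist1h1c 0.191, Hist1h2bc 0.451, Col4a1 0.646, Nnat 1.42 and Srgn 5.08. Quantile normalization gave Uhrf1 (iEpiSC minus iPSC) -0.0431 and Dnmt3a (EpiSC minus iPSC) 0.00699, and medians of 0.0854 for the glycolysis list of EpiSC minus iPSC and -0.0635 for the oxidase list of iEpiSC minus EpiSC. Without iPSC clones 1 and 9, Dnmt3a was at -0.0669 for iEpiSC minus iPSC. With a library left out in turn, H19 ran from -0.24 to 0.577 and Uhrf1 from -0.0626 to 0.0872 for iEpiSC minus iPSC, Dnmt3a from -0.212 to 0.0579 for EpiSC minus iPSC, and Dnmt3l from -0.051 to 0.459 for iEpiSC minus EpiSC. The camera direction of some lists turned while their median kept its sign. With a library left out in turn, the medians of lists that turned ran from -0.141 to 0.0575 (paternally expressed) and -0.181 to 0.209 (Activin and Nodal; 0.0342 with a pseudocount of 0.1) for iEpiSC minus iPSC. They ran from -0.371 to -0.0346 (mesendoderm) and -0.0988 to 0.146 (histones) for EpiSC minus iPSC, and from 0 to 0.0823 (naive) and -0.248 to -0.0818 (neural) for iEpiSC minus EpiSC.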

Other observations

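The gene sets and tests in this part were all chosen after the values were seen. Some genes stood far above the other clones in iPSC clone 9; those given here were picked by their values and were not tested as a group. Krt14, a keratin of basal epidermis, was at 99.1 RPKM (0.163 to 0.504 RPKM in the other clones), Krt13, a keratin of stratified mucosa, at 47.9 RPKM (0.0515 to 0.329), Krtdap at 437 RPKM (5.18 to 22.5) and Tgm2, transglutaminase 2, at 192 RPKM (1.08 to 6.21). Genes of other kinds stood apart too, such as Aldh3a1, an aldehyde dehydrogenase, at 113 RPKM (0.559 to 0.808), the receptor tyrosine kinase Ret at 33.9 RPKM (0.909 to 2.33) and Hoxa9 at 12.3 RPKM (0.0248 to 0.296). The reprogramming factors Myc and Klf4 were at 226 and 183 RPKM there, against 46.2 to 55.4 and 72.3 to 88.5 RPKM in the other clones. Sox2 was at 113 RPKM in clone 9 and 142 to 152 RPKM in the others.

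Meg3, Rian and Mirg were lower in iEpiSCs than in EpiSC 12, though not past the threshold. RNA of fibroblasts in the EpiSC library could carry 2.34%, 16.8% and 10.9% of their values, scaled by the most favourable marker. This assumes the same fibroblast profile in every library. The value for Meg3 rests on 0.0774 RPKM in iEpiSC F1 and that for Mirg on 0.234 RPKM in iEpiSC B1, both near the floor. With the fibroblast score as a covariate the changes of iEpiSC minus EpiSC were -7.19 ± 2.11 (Meg3), -6.27 ± 2.16 (Rian) and -4.59 ± 1.44 (Mirg), as large as without it. The median of the fibroblast list went from -1.97 to 0.104, which follows from the score being the mean of that list. The slope of the score rests on the iPSC and iEpiSC clones alone, so the changes of the 3 genes do not decide the question. The 3 genes passed in neither fit (adjusted p = 0.426 to 0.429 with it), so fibroblast RNA is not excluded for them. For H19 (bound 53.9%) and Igf2 (156%) the changes went from -3.31 ± 0.75 to -1.04 ± 1.06 and from -1.34 ± 0.47 to -0.09 ± 0.76, and it stays open there too. Medium, passage and origin differed with the group and remain untested, as does a difference in methylation at the locus.

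Immediate-early genes (19 genes, 18 tested) were listed after their values in EpiSC 12 were seen, so no test of the list is given. Their median log2 change was 2.01 against iPSCs, with 11 called higher, and -2.14 for iEpiSC minus EpiSC, with 5 called lower. By the same bound RNA of fibroblasts could carry 93% of the value of the median gene (17.6% for Fosb, 12.4% for Egr2, 5.83% for Egr3, 5.9% for Egr4, and 0 for Npas4 and Nr4a2). The values for Egr2, Egr3 and Egr4 rest on 0.4153 RPKM in iPSC 7, 0.05507 RPKM in iEpiSC B1 and 0.2218 RPKM in iPSC 9, all near the floor. Those of 0 rest on Npas4 listed at 0 in iPSC 7 and Nr4a2 in iEpiSC F1, which can be failed estimates. With the fibroblast score as a covariate the median change against iPSCs was 1.26, with 1 gene called, Egr4 (3.96 ± 0.26 without it, 4.02 ± 0.41 with it, adjusted p = 0.0352). The median SE became 0.483 instead of 0.391, which ends calls too, so fibroblast RNA stays open for the list as a whole. Handling at harvest cannot be told apart from the group, since there was 1 EpiSC library. No biological explanation was tested.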
